A study of Mus musculus with 12 samples.

How the data were processed

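The data are the deposited gene counts of 12 heart libraries, 3 in each of 4 groups given by diet (control or Western) and pregnancy state (nonpregnant or postpartum day 1), grouped by their labels. Per the labels, RNA was extracted with the Qiagen RNeasy kit and libraries were made with the NEBNext Ultra RNA kit for Illumina. The authors processed the reads with FastQC, STAR 2.5.2b and featureCounts of Subread 1.5.2 on the GRCm38 (mm10) genome, per the labels. The deposited values are raw read counts per gene, with no normalization. The strand setting, the read length and the annotation release are not given in the sources used here, so genes that overlap on opposite strands and close paralogs may share counts. The raw reads were lost according to the series and were not used here.

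Counts were joined by gene identifier. The file of Western diet postpartum replicate 1 lists its genes in another order and with other line ends than the rest, and holds the same identifiers. The files hold 49315 genes, of which 345 had no gene symbol in the annotation used here; these took 0.0218% to 0.0248% of each library's counts. They stayed in the tests but are not named. Library totals were 22754591 to 29492416 counts, and the upper limit of a count of 0, 3 counts of the total, was 0.102 to 0.132 CPM, for counting error only. Reads carry no molecular identifiers, so such limits take no account of duplicates.

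Genes with low counts were removed with edgeR's filterByExpr by group (minimum count 10, minimum total 15), which left 15476 genes. Libraries were scaled by the trimmed mean of M-values (TMM), and CPM values use these scaled library sizes. All libraries were fitted in one edgeR quasi-likelihood model with a mean per group (common biological coefficient of variation 9.62%), and contrasts were tested with its F test, two-sided, with Benjamini-Hochberg adjustment over all genes within each comparison at a threshold of 0.05. The 8 comparisons were postpartum against nonpregnant on each diet, Western against control diet in each pregnancy state, Western diet postpartum against control diet nonpregnant, the interaction, and the effects of pregnancy and of diet averaged over the other factor. They are 1 family of related contrasts of the same libraries, adjusted separately. Standard errors of log2 fold changes are the fold change over the square root of F. An estimated fold change was kept unshrunken.

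Gene lists were tested with camera (limma) on the counts with a preset inter-gene correlation of 0.01, Benjamini-Hochberg over all lists within a comparison, and again with an estimated correlation. Of 38 lists fixed, 35 had at least 5 measured members and were tested, 21 of functions and 14 of cell types. Not tested were the thymocyte markers (2 of 7 measured), the mesothelial and epicardial markers (4 of 12) and the lung epithelium markers (0 of 10). Each list's members were counted past the all-gene threshold and adjusted over the list alone. Fry gave a further count of lists that move 1 way. The comparisons, the tests, the lists and the rule for named genes were fixed before the data were examined. The rule names, in each comparison, the 10 rising and 10 falling genes with the smallest p among those past the threshold whose CPM did not overlap between the groups (for averaged effects, with the same direction in both strata), at 1 CPM or more in the higher group and with a symbol that is not a predicted or clone name. For 3 libraries against 3, no overlap has a chance share of 10%. Where none passed, 3 per direction are named. The rule adds up to 4 members with the smallest p of each list past camera's threshold, and follows 17 genes of cardiac stress, matrix and metabolism in every comparison. Of these additions the text prints those that passed or bear on a group described, and leaves out values near 0. 1 gene is not reported here, though it stayed in all tests and counts.

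The procedure was tested on simulated data, drawn for the 12 libraries with their sizes and with the means and dispersions of the genes, and with changes set in 1 group of 3; 15310 genes were tested. Of genes set to change, edgeR recovered 36 of 67 at 1.5-fold, 54 of 67 at 2-fold and 64 of 66 at 4-fold. It made 9 calls among 15246 genes set to no change, all these totals being counted before the filter on low counts. DESeq2 recovered 38, 54 and 63 with 23 such calls, and limma-voom 36, 55 and 64 with 9. Camera passed a list moved by 0.3 on the log2 scale and did not pass a list left unchanged. The simulated genes were drawn independently, so this does not test camera on lists whose members move together.

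The alternatives tried were DESeq2's size factors in edgeR, no filter on low counts, a filter of 1 CPM in at least 3 libraries, edgeR's robust option, library sizes without mitochondrial genes, a fit of only the groups compared, DESeq2, limma-voom, an estimated correlation or fry for the lists, and each library left out in turn. Leaving out control diet postpartum replicate 3 together with control diet nonpregnant replicate 1 was added after the data were seen. Labels were also regrouped, over all 10 splits for 3 against 3 libraries and 100 drawn regroupings for the other comparisons. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.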

Results

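RNA was sequenced from 12 heart libraries of female C57BL/6J mice, 3 in each of 4 groups. The mice ate a control diet with 10% of its energy as fat, or a Western diet with 45% as fat and 17% as sucrose, for 15 weeks before breeding. On each diet, hearts came from females that were not bred or from females on day 1 after delivery, called nonpregnant and postpartum here. All were aged 27 to 29 weeks. The series states its purpose as asking whether metabolic syndrome, a cluster of disorders such as obesity and insulin resistance, causes harmful remodelling of the heart in pregnancy. Total counts per library ran from 22754591 to 27118406 in control diet nonpregnant hearts and from 25611052 to 29492416 in control diet postpartum hearts. They ran from 22978995 to 28398335 in Western diet nonpregnant hearts and from 22912896 to 25472803 in Western diet postpartum hearts. Levels are given as CPM, counts scaled for library size. A gene with no counts in a library could still lie at up to 0.102 to 0.132 CPM, a limit that covers counting error only. Each library's title carries a number of its own, which reads as an animal number. The postpartum numbers all come before the nonpregnant ones, so anything that goes with this order cannot be told apart from pregnancy. The labels do not state that the libraries of a group come from separate animals, and the p-values measure only the spread between these libraries.

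The mitochondrial gene mt-Co1, a subunit of cytochrome c oxidase, was the most abundant in each of the 12 libraries. Myh6, the adult cardiac myosin heavy chain, stood at 35640 ± 1658 CPM (SD, n = 3) in control diet nonpregnant hearts. The mitochondrially encoded genes took 20.02 ± 0.24% of counts (SD, n = 3) in control diet nonpregnant and 19.3 ± 0.14% in control diet postpartum hearts. They took 20.9 ± 0.42% in Western diet nonpregnant and 21.1 ± 0.59% in Western diet postpartum hearts. Control diet postpartum replicate 3 carried genes of fat tissue. There Ucp1, the uncoupling protein of brown fat, stood at 73.1 CPM against at most 0.545 CPM in the other 11 libraries. Cfd, the secreted adipsin of fat cells, stood at 72.6 against 1.51 CPM, Adipoq, the hormone adiponectin, at 19.6 against 0.543 CPM, and Plin1, a lipid droplet coat protein, at 12.2 against 0.698 CPM. Of the 15 genes of the white adipocyte list present in the files, 5 reached 1 CPM in all 11 other libraries and 2 also belong to another list. For the 11 genes of the brown adipocyte list these numbers were 6 and 3. Control diet nonpregnant replicate 1 differed from replicates 2 and 3 of its group by a chi-square per degree of freedom of 16.7 and 16.4, against 4.03 between those. Western diet postpartum replicate 2 differed from its replicates by 14.2 and 12.9, against 7.04. The first 3 principal components held 17.7%, 15.4% and 12.5% of the variance.

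**Figure D1:**
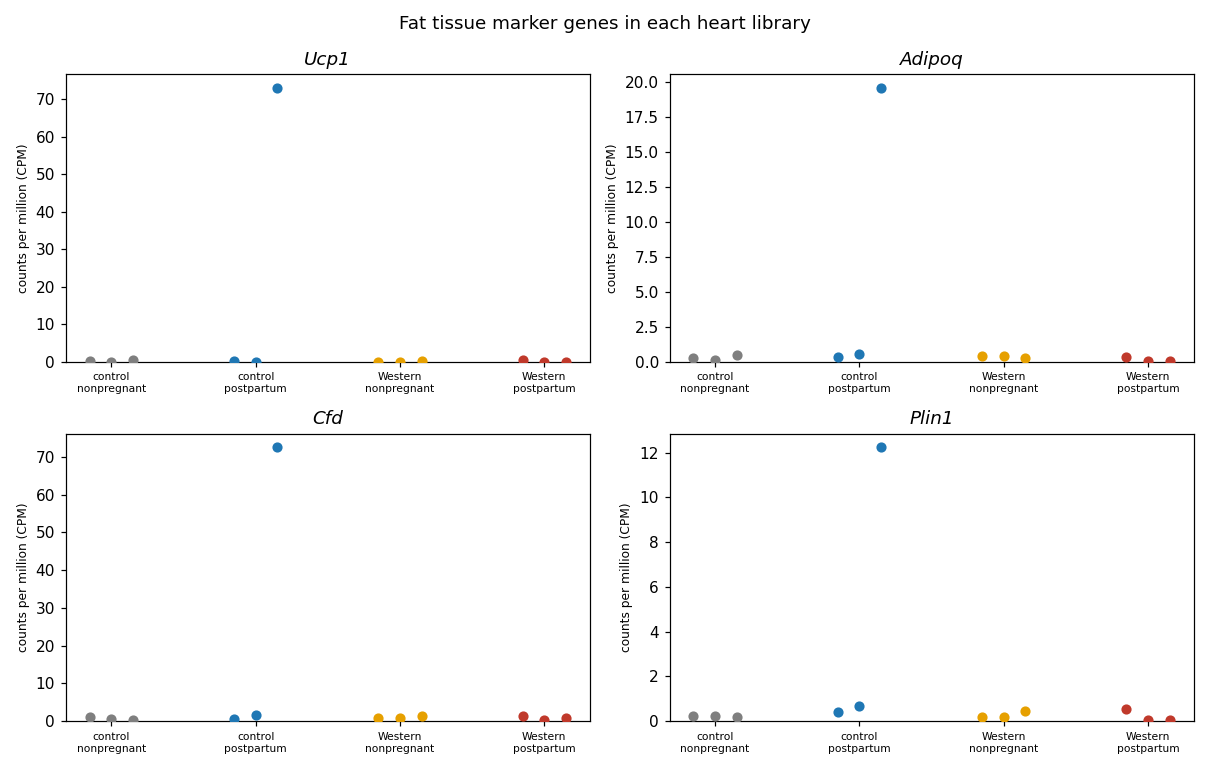
Normalised CPM (vertical axis) of 4 fat tissue genes in the 12 heart libraries, by group; each point is 1 library, with replicates 1 to 3 from left to right. Control diet postpartum replicate 3 stands apart, with Ucp1 at 73.1 CPM against at most 0.545 CPM elsewhere.

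The first comparison sets postpartum against nonpregnant hearts on the control diet. Collagens and other genes of the scar-forming matrix rose. Col1a1, a chain of type I collagen, went from 67.6 ± 12.7 to 123 ± 20.9 CPM (SD, n = 3; log2 fold change 0.86, SE 0.15, adjusted p = 0.0409). Sparc, a collagen-binding matrix protein, rose by 0.62 and Serpinh1, the chaperone that folds collagen, by 0.48 on the log2 scale. Also higher were Col1a2 (0.75), Col6a3 (0.86) and Adamts2, which trims procollagen (0.55). Of 18 macrophage and monocyte markers 3 rose, Cd68 (0.80) and the complement chains C1qa (0.52) and C1qb (0.48), and the list's own call was lost at adjusted p = 0.0978 with an estimated correlation. The platelet chemokine Pf4 rose by 0.58. Stbd1, a glycogen-binding protein, rose by 0.73, as did the annexin Anxa2 (0.42) with its partners S100a10 (0.45) and the related S100a11 (0.43). The actin-binding Dbn1 (0.64) and Cotl1 (0.65), the scavenger receptor-like Ssc5d (0.72) and the interferon-induced Ifi27l2a (0.89) were higher as well. Among the 5 genes that fell was Myh7, the slow myosin heavy chain, which is raised in failing mouse hearts (-0.33). The others were the galectin Lgals4 (-1.03), Fryl (-0.36), Rnf166 (-0.40) and the mitochondrial transfer RNA mt-Te (-0.35), a short RNA that this kind of library captures poorly.

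Among the gene lists, the extracellular matrix and fibrosis list had 38 of 41 genes with positive changes and a median log2 fold change of 0.48. Of these 11 rose over all genes tested and 27 adjusted over the list alone (camera adjusted p = 4.30e-40, and adjusted p = 0.0329 with an estimated correlation). The fibroblast markers stood at a median of 0.39, with 2 of 15 risen over all genes and 9 adjusted over the list alone (adjusted p = 8.24e-12, and adjusted p = 0.0329 with an estimated correlation). The 10 of them outside the matrix list stood at 0.18, so the calls of these lists share genes. The circadian clock list stood at -0.33 (adjusted p = 1.59e-08, and adjusted p = 0.0329 with an estimated correlation). Over all genes 0 of its 20 members passed, and adjusted over the list alone 10 fell and 1 rose. Ciart stood at -1.11 (adjusted p = 0.104) and Dbp, a transcription factor with a strong daily rhythm, at -0.83 (adjusted p = 0.149). The cell cycle and DNA replication list stood at a median of 0.84, with 0 of 32 genes past the test over all genes and 19 risen adjusted over the list alone. Its call (adjusted p = 7.60e-23) was lost at adjusted p = 0.0978 with an estimated correlation. The mitotic genes Birc5 and Top2a stood at 1.82 (adjusted p = 0.0883) and 1.56 (0.138), and E2f1, a driver of replication, at 1.30 (0.0692). Macrophage and monocyte markers stood at 0.41, with 3 of 18 genes risen over all genes and 6 adjusted over the list alone (adjusted p = 2.02e-12, but adjusted p = 0.0978 with an estimated correlation). The fetal and hypertrophic gene program stood at 0.30, although Myh7 fell (adjusted p = 0.00148, but adjusted p = 0.188 with an estimated correlation). Nppb, the natriuretic peptide that marks wall stress, stood at 107 ± 37.9 and 250 ± 72.9 CPM (SD, n = 3; log2 fold change 1.22, adjusted p = 0.271). Endothelial markers stood at 0.02 (adjusted p = 0.329). With 1 library left out, the fetal and hypertrophic gene program stood at 0.12 and 0.17 without control diet nonpregnant replicates 1 and 3, and cell cycle and DNA replication at 1.29 without control diet nonpregnant replicate 1. White adipocyte markers stood at a median of 1.07 with a mean of 2.08 (adjusted p = 0.0570), in the comparison that holds the library with fat tissue genes.

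The edgeR quasi-likelihood test called 37 of 15476 genes on the control diet, 32 higher and 5 lower postpartum, 3 of them by at least 2-fold. An unadjusted p under 0.05 was reached by 1930 genes, where chance alone would give 773.8. Camera called 12 lists, 7 up and 5 down, of which 3 held with an estimated correlation and 6 were lost without at least 1 library. Among those 6 were adult sarcomere and calcium handling, cardiac ion channels and gap junctions, and fatty acid oxidation and PPAR alpha targets. The rest of the 6 were the interferon-stimulated genes, the mitochondrially encoded genes, and the unfolded protein and integrated stress response. None of the 23 named calls held without each library in turn. A fit with 1 library fewer also has less power, here and below. A lost call therefore does not by itself show that the call rested on that library. The gene count was 0 without control diet postpartum replicate 1 or control diet nonpregnant replicate 2, and 1 without control diet postpartum replicate 3 or control diet nonpregnant replicate 3. It was 205 without control diet nonpregnant replicate 1, and 74 without control diet postpartum replicate 3 and control diet nonpregnant replicate 1 together, called the control pair below.

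**Figure D2:**
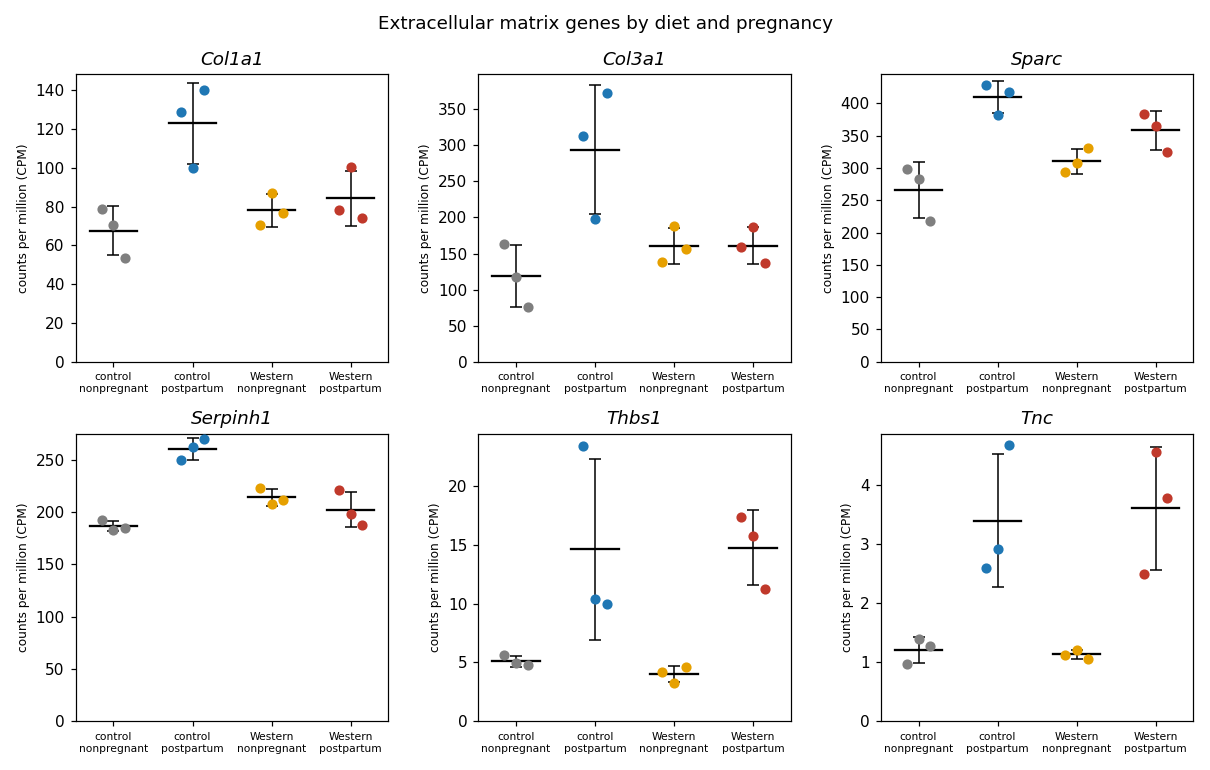
Normalised CPM (vertical axis) of 6 extracellular matrix genes in the 4 groups; points are libraries, the horizontal line is the group mean and the bar 1 SD (n = 3). Col1a1 averaged 123 CPM in control diet postpartum and 84.2 CPM in Western diet postpartum hearts, whereas Thbs1 averaged 14.6 and 14.8 CPM there.

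The same comparison was made between hearts from mice on the Western diet. Thbs1, a matrix protein of injury and stretch, rose from 4.01 ± 0.68 to 14.8 ± 3.16 CPM (SD, n = 3; log2 fold change 1.88, SE 0.30, adjusted p = 0.0271). Tnc, a matrix protein re-expressed in remodelling hearts, rose by 1.67 and Ccl2, a chemokine that recruits monocytes, by 1.69. Of 25 antioxidant and NRF2 targets 4 rose, Gclm of glutathione synthesis (0.82), Srxn1 (0.78), heme oxygenase Hmox1 (0.79) and Txnrd1 (0.41), and the list's own call was lost at adjusted p = 0.230 with an estimated correlation. Higher were also the pyrimidine salvage kinase Uck2 (1.18), the ribosome factor Rrp12 (0.91), the translation brake Eif4ebp1 (0.50) and the AP-1 factor Fosl2 (0.60). Popdc3 (0.65), Rusc2 (0.53), Ybx3 (0.40), Bsg (0.38), Sord (0.37) and Pdk1 (0.36) rose as well. The clock outputs Ciart (-1.91), Dbp (-1.48) and Bhlhe41 (-0.67) fell, as did Tcap, which anchors titin at the Z-disc (-0.94), and the heart growth factor Fgf16 (-0.82). Further falls were those of Plxnb1 (-0.75), Pdcd4 (-0.71), Carns1 (-0.64), Reep1 (-0.62), Hes6 (-0.59) and the smooth muscle gene Smtn (-0.49). Nppb stood at 93.5 ± 30.9 and 386 ± 247 CPM (SD, n = 3; log2 fold change 2.04, adjusted p = 0.0588).

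Of the lists on the Western diet, cytokines and acute inflammation kept its call with an estimated correlation (median 0.27, camera adjusted p = 1.02e-05, and adjusted p = 0.0420 with an estimated correlation). Of its 24 genes 1 rose over all genes and 8 adjusted over the list alone. The antioxidant and NRF2 targets had 4 of 25 genes risen by either adjustment (median 0.12, adjusted p = 5.14e-05, but adjusted p = 0.230 with an estimated correlation). The circadian clock list had 3 of 20 genes fallen over all genes, and 9 fallen with 4 risen adjusted over the list alone. Its median was -0.24 (adjusted p = 0.000434, but adjusted p = 0.209 with an estimated correlation). Interferon-stimulated genes, which limit virus growth, stood at -0.36 (adjusted p = 3.27e-08, but adjusted p = 0.457 with an estimated correlation). None of the 30 passed over all genes and 3 fell adjusted over the list alone. The median was -0.20 without Western diet nonpregnant replicate 1, and -0.54 and -0.24 without Western diet postpartum replicates 2 and 3. Lymphocyte markers stood at -0.85 over 12 genes (adjusted p = 2.99e-05, but adjusted p = 0.230 with an estimated correlation). With the filter of 1 CPM they stood at -0.32 and that call was lost too (adjusted p = 0.0948). Fatty acid oxidation and PPAR alpha targets stood at 0.16, with 1 of 40 genes risen over all genes and 8 adjusted over the list alone (adjusted p = 7.16e-07, but adjusted p = 0.454 with an estimated correlation). The extracellular matrix and fibrosis list stood at 0.12, with 2 of 41 genes risen, Thbs1 and Tnc, and 7 adjusted over the list alone (adjusted p = 0.000108, but adjusted p = 0.596 with an estimated correlation). The fetal and hypertrophic gene program stood at 0.37, with 0 of 19 genes past the test over all genes and 7 risen adjusted over the list alone (adjusted p = 7.59e-05, but adjusted p = 0.209 with an estimated correlation). It stood at 0.24 without Western diet postpartum replicate 1, and fatty acid oxidation and PPAR alpha targets at 0.10 without replicate 3 of that group. The extracellular matrix and fibrosis list stood at 0.04 and 0.20 without Western diet nonpregnant replicates 1 and 3, and cytokines and acute inflammation at 0.43 without replicate 2 of that group.

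In this comparison 91 genes passed, 55 higher and 36 lower postpartum, 17 by at least 2-fold, and 2281 had an unadjusted p under 0.05. Camera called 14 lists, of which 1 held with an estimated correlation and 5 were lost without at least 1 library. None of the 28 named calls held without each library in turn. With 1 library left out, 7 genes passed without Western diet postpartum replicate 1, 472 without Western diet postpartum replicate 2, and 0 without Western diet postpartum replicate 3. None passed without any 1 of the Western diet nonpregnant replicates 1, 2 and 3.

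After pregnancy the Western diet raised transcripts of several enzymes and regulators of fatty acid use, tested gene by gene. The call of their list was lost at adjusted p = 0.0510 with an estimated correlation. Acot1, which splits acyl-CoA, rose from 9.58 ± 0.88 to 48.2 ± 20.1 CPM (SD, n = 3; log2 fold change 2.33, SE 0.26, adjusted p = 0.00189). Its relative Acot2 rose by 1.32; the 2 are near-identical neighbours, so reads shared between them leave each value uncertain. The PPAR alpha targets Pdk4, which blocks glucose oxidation, and Angptl4, an inhibitor of lipoprotein lipase, rose by 2.35 and 2.90. Each call ended when any 1 of several libraries was left out. That of Pdk4 was lost without control diet postpartum replicate 2 (adjusted p = 0.0704) or 3 (0.0888) or Western diet postpartum replicate 3 (0.0692), at values of 2.15 to 2.44. That of Angptl4 was lost without control diet postpartum replicate 1 (0.0809), 2 (0.064) or 3 (0.0888) or Western diet postpartum replicate 3 (0.0866), at values of 2.825 to 2.96. Both calls held without Western diet postpartum replicate 2 (0.0210 and 0.0289), with values of 1.68 and 2.34. With edgeR's robust option both were lost (0.102 and 0.103). Of 15 alternatives in all, the libraries left out included, the call of Angptl4 was lost under 7 and that of Pdk4 under 6. Further rises were those of the peroxisome gene Pex11a (0.62), the acyl-CoA synthetase Acsf2 (0.78), the triglyceride lipase Pnpla2 (0.89) and the peroxisomal catalase Cat (0.62). Mthfd2, an enzyme of mitochondrial one-carbon metabolism, rose by 1.47, the sodium channel subunit Scn4b by 0.78 and Lgals4 by 1.25. The oncostatin M receptor Osmr (0.75), Ptp4a1 (0.67), Plbd1 (0.55), the mTOR inhibitor Deptor (0.52), mt-Te (0.47) and the squalene synthase Fdft1 (0.44) were higher. Lower were Lgi3 (-1.34), Ston2 (-1.20), Lrrc4b (-0.998), Tmem35a (-0.92), the cell division gene Cenpf (-0.74), Fgf16 (-0.74) and Ppp1r14c (-0.70). Brain-type creatine kinase Ckb (-0.64), Ndrg4 (-0.56), Hsd17b12 of fatty acid elongation (-0.54), Smtn (-0.46) and the collagen chaperone Serpinh1 (-0.36) fell as well. Nppa, the atrial natriuretic peptide, stood at 92.9 ± 7.59 on the control and 51.7 ± 9.36 CPM on the Western diet (SD, n = 3; log2 fold change -0.85, adjusted p = 0.0629).

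Fatty acid oxidation and PPAR alpha targets had 39 of 40 genes with positive changes after pregnancy, at a median of 0.43. Of these 15 rose over all genes and 35 adjusted over the list alone (camera adjusted p = 2.27e-49, but adjusted p = 0.0510 with an estimated correlation). The mitochondrially encoded genes were positive for all 13, with mt-Nd2 of complex I risen (0.31) and 6 risen adjusted over the list alone. Their median was 0.22 (adjusted p = 2.08e-07, but adjusted p = 0.166 with an estimated correlation), beside the higher mitochondrial share of counts on the Western diet. Endothelial markers stood at 0.20, with 0 of 15 past the test over all genes and 8 risen adjusted over the list alone (adjusted p = 2.08e-07, but adjusted p = 0.0987 with an estimated correlation). The extracellular matrix and fibrosis list stood at -0.26 (adjusted p = 2.08e-07, but adjusted p = 0.391 with an estimated correlation). Serpinh1 fell over all genes, and 12 fell and 1 rose adjusted over the list alone. Col1a1 stood at -0.55 (adjusted p = 0.109) and Col3a1 of type III collagen at -0.87 (adjusted p = 0.112). None of the 32 cell cycle and DNA replication genes was positive, at a median of -0.37 (adjusted p = 3.28e-06, but adjusted p = 0.432 with an estimated correlation). Without control diet postpartum replicate 1 that median was -0.13. The antioxidant and NRF2 targets had a median of 0.12 and a mean of -0.13 with camera's direction up (adjusted p = 0.000204, but adjusted p = 0.192 with an estimated correlation). This list lay at 0.31 in control diet postpartum replicate 3 against -0.07 and -0.12 in its replicates, and without that library its median was 0.12 (adjusted p = 6.29e-05). Sterol and fatty acid synthesis stood at -0.23 over 25 genes, although its called member Fdft1 rose (adjusted p = 0.00356, but adjusted p = 0.391 with an estimated correlation). The list moved with the fat tissue genes of control diet postpartum replicate 3, without which it stood at -0.10 (adjusted p = 0.134). Brown adipocyte markers stood at -0.51 with Slc36a2 fallen (-0.51), and their call (adjusted p = 0.0470, but adjusted p = 0.391 with an estimated correlation) moved with that library too. Without it they stood at -0.01 (adjusted p = 0.703), and their call was also lost without Western diet postpartum replicate 1 (0.0772) or 2 (0.179). It was lost as well under 5 of the other settings (adjusted p = 0.0528 to 0.156). White adipocyte markers had a median of -0.37 and a mean of -2.03 while camera's direction was up (adjusted p = 0.990).

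**Figure D3:**
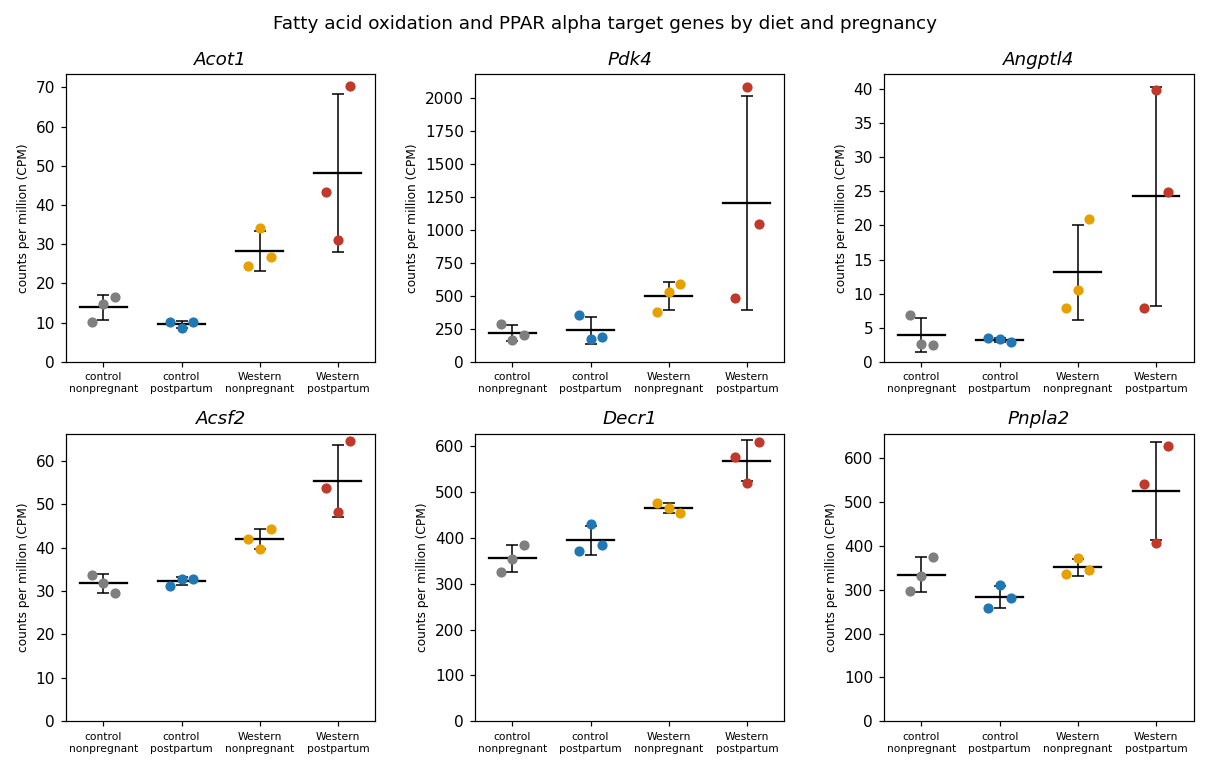
Normalised CPM (vertical axis) of 6 genes of fatty acid use in the 4 groups; points are libraries, the horizontal line is the group mean and the bar 1 SD (n = 3). Acot1 averaged 13.8 CPM in control diet nonpregnant and 48.2 CPM in Western diet postpartum hearts.

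After pregnancy 136 genes differed between the diets, 100 higher and 36 lower on the Western diet, 27 by at least 2-fold, with 2259 at an unadjusted p under 0.05. Of the 31 named calls 14 held without each library in turn, those of Acot1, Acot2, Acsf2, Cat, Ckb, Deptor, Lgals4, Lgi3, mt-Te, Mthfd2, Pex11a, Plbd1, Pnpla2 and Ptp4a1. Camera called 15 lists, none of which held with an estimated correlation, and 6 were lost without at least 1 library. Gene calls numbered 79 and 74 without control diet postpartum replicates 1 and 3, and 82, 490 and 30 without Western diet postpartum replicates 1, 2 and 3. They numbered 124 without the control pair.

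Without pregnancy 9 genes were called between the diets by edgeR and 95 by DESeq2. The sodium channel subunit Scn4b rose from 49.37 ± 4.003 to 89.58 ± 15.28 CPM (SD, n = 3; log2 fold change 0.86, SE 0.12, adjusted p = 0.0363) and the peroxisome gene Pex11a by 0.46. The retinol and aldehyde dehydrogenases Adh1 (0.82) and Aldh1a1 (0.61), the adhesion protein Lims2 (0.41) and Ramp2, a receptor partner of adrenomedullin in vessels (0.41), rose as well. Abat, which breaks down the transmitter GABA, fell by 1.37 and Ndrg4 by 0.56. Values that did not pass were Angptl4 at 1.71 (adjusted p = 0.326, and at 2.40 without control diet nonpregnant replicate 1), Pdk4 at 1.20 (0.372), Acot1 at 1.04 (0.204) and Nppa at -0.96 (0.142). Interferon-stimulated genes were positive for all 30 members at a median of 0.50 (camera adjusted p = 2.43e-22, but adjusted p = 0.213 with an estimated correlation). None passed over all genes and 9 rose adjusted over the list alone. Ifi44 stood at 0.88 (adjusted p = 0.276) and Rsad2 at 0.70 (0.28). Western diet nonpregnant replicate 1 had the highest level of this list in the 12 libraries, 0.65 on the log2 scale above their mean, and without it the median was 0.33. Fatty acid oxidation and PPAR alpha targets were positive for 36 of 40 genes at a median of 0.21, with 1 risen over all genes and 6 adjusted over the list alone (adjusted p = 2.56e-15, but adjusted p = 0.213 with an estimated correlation). Endothelial markers stood at 0.15, with Ramp2 risen over all genes, and 6 risen and 1 fallen adjusted over the list alone (adjusted p = 9.57e-06, but adjusted p = 0.213 with an estimated correlation). The cardiac ion channels and gap junctions stood at -0.14, although their called member Scn4b rose (adjusted p = 0.000159, but adjusted p = 0.0851 with an estimated correlation). Fibroblast markers stood at 0.21 (adjusted p = 3.06e-05, but adjusted p = 0.213 with an estimated correlation), and macrophage and monocyte markers at 0.20 (adjusted p = 0.000146, but adjusted p = 0.473 with an estimated correlation). Without control diet nonpregnant replicate 3 the ion channels stood at -0.09, the fibroblast markers at 0.12 and the macrophage and monocyte markers at 0.13. The last stood at 0.33 and 0.12 without replicates 1 and 2 of that group.

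The test without pregnancy called 9 genes, 7 higher and 2 lower on the Western diet, 2 of them by at least 2-fold, and 1483 had an unadjusted p under 0.05. Camera called 14 lists, none of which held with an estimated correlation, and 5 were lost without at least 1 library. None of the 8 named calls held without each library in turn. The gene count was 0 without control diet nonpregnant replicate 2 or 3 or Western diet nonpregnant replicate 2, and 1 without Western diet nonpregnant replicate 3. It was 3 without control diet nonpregnant replicate 1, 4 without Western diet nonpregnant replicate 1, and 15 without the control pair, 6 of them among the 9.

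The series sets Western diet pregnancies against nonpregnant controls as well, which joins both factors. Mthfd2 of mitochondrial one-carbon metabolism stood 4.73-fold higher in Western diet postpartum than in control diet nonpregnant hearts, at 13.6 ± 3.30 against 2.87 ± 0.25 CPM (SD, n = 3; log2 fold change 2.24, SE 0.20, adjusted p = 0.000232). The gene lies on chromosome 6 from 83305691 to 83325908 in the GRCm38 (mm10) build. Pdk4 (2.48; chromosome 6, 5483351 to 5496309) passed, but not without control diet nonpregnant replicate 2 (adjusted p = 0.067) or 3 (0.051) or with edgeR's robust option (0.0564), and it stood at 1.82 without Western diet postpartum replicate 2. Angptl4 (2.59; chromosome 17, 33773750 to 33781575) passed, but not without control diet nonpregnant replicate 2 (0.105) or 3 (0.0853), without Western diet postpartum replicate 3 (0.0684) or with the robust option (0.0888), and it stood at 3.27 without control diet nonpregnant replicate 1. The call of Angptl4 was lost under 6 of 15 alternatives in all. Higher were also Acot1 (1.81), Acsf2 (0.80) and the beta-oxidation enzymes Decr1 (0.68) and Hadhb (0.41). Phgdh (1.48) and Asns (1.31), of serine and asparagine synthesis, rose as well. So did Tnc (1.58), Thbs1 (1.53; chromosome 2, 118111876 to 118127133), elastin Eln (0.71), Hmox1 (0.79), the calcineurin target Rcan1 (0.74) and Nppb (1.85, adjusted p = 0.0431). The endothelial junction genes Cldn5 (0.75) and Pecam1 (0.34), the clock repressor Nfil3 (1.06), Lims2 (0.53), Bsg (0.44) and S100a11 (0.44) were higher too. Clock outputs fell, with Ciart at -2.04, Dbp at -1.64 and Bhlhe41 at -0.67. Tcap (-1.05), the slow skeletal troponin T Tnnt1 (-1.13), Fgf16 (-1.10), the calcium pump regulator Pln (-0.27) and Myh7 (-0.26) were lower. The T-type calcium channel Cacna1h (-0.56), the ventricular gap junction protein Gja1 (-0.51), the potassium channel Kcnj5 (-0.45) and the insulin-responsive glucose transporter Slc2a4 (-0.44) fell too. Abat (-1.85), Lrrc4b (-1.26), Cenpf (-1.08), Gsg1l (-0.86), Carns1 (-0.76) and Plekha6 (-0.52) were lower.

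In that joint comparison 4 list calls held with an estimated correlation. Cardiac ion channels and gap junctions stood at -0.32 (camera adjusted p = 1.20e-06, and adjusted p = 0.0198 with an estimated correlation). Of their 26 genes 3 fell and 1 rose over all genes, and 13 fell and 1 rose adjusted over the list alone. Cytokines and acute inflammation stood at 0.29, with 2 risen over all genes and 9 adjusted over the list alone (adjusted p = 7.16e-05, and adjusted p = 0.0452 with an estimated correlation). Endothelial markers stood at 0.24, with 5 of 15 risen over all genes and 11 adjusted over the list alone (adjusted p = 6.84e-09, and adjusted p = 0.0474 with an estimated correlation). The clock list stood at -0.41, with 6 of 20 fallen and 1 risen over all genes, and 11 fallen and 4 risen adjusted over the list alone (adjusted p = 1.72e-06, and adjusted p = 0.0474 with an estimated correlation). Fatty acid oxidation and PPAR alpha targets had 16 of 40 genes risen over all genes, and 27 risen and 1 fallen adjusted over the list alone. Their median was 0.38 (adjusted p = 5.83e-27, but adjusted p = 0.0557 with an estimated correlation). The extracellular matrix and fibrosis list stood at 0.26, with 4 of 41 genes risen over all genes and 9 adjusted over the list alone (adjusted p = 4.87e-09, but adjusted p = 0.279 with an estimated correlation). Adult sarcomere and calcium handling stood at -0.15, with 2 of 24 genes fallen over all genes and 8 adjusted over the list alone (adjusted p = 5.65e-06, but adjusted p = 0.279 with an estimated correlation). Without control diet nonpregnant replicate 3 this list stood at -0.09 and the extracellular matrix and fibrosis list at 0.15. Without replicate 1 of that group the latter stood at 0.42 and cytokines and acute inflammation at 0.45, which stood at 0.18 without Western diet postpartum replicate 2.

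The joint test called 406 genes, 224 higher and 182 lower, 65 by at least 2-fold, with 2811 at an unadjusted p under 0.05. Of the 40 named calls 22 held without each library in turn. They were Abat, Acot1, Acsf2, Asns, Bsg, Carns1, Cenpf, Ciart, Dbp, Decr1, Fgf16, Gsg1l, Hadhb, Lims2, Lrrc4b, Mthfd2, Phgdh, Plekha6, S100a11, Tcap, Tnc and Tnnt1. Camera called 17 lists, of which 5 were lost without at least 1 library. The gene count was 87, 764 and 115 without Western diet postpartum replicates 1, 2 and 3, and 89 and 146 without control diet nonpregnant replicates 2 and 3. It was 457 without the control pair.

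Whether the diet altered the heart's response to pregnancy is the interaction of diet and pregnancy. For collagen genes the difference in log2 fold change, Western diet minus control diet, was -0.75 for Col1a1 (adjusted p = 0.394) and -1.30 for Col3a1 (0.376). It was -0.83 for Col16a1 (0.35) and -0.56 for Serpinh1 (0.234). For metabolic genes it was 1.29 for Acot1 (adjusted p = 0.377) and 0.82 for Pnpla2 (0.357). Other values with a small p were 1.15 for Dusp18, 0.66 for Myh14, 0.54 for Rreb1 (each with adjusted p = 0.35) and -0.46 for Smtn (0.357). The edgeR quasi-likelihood test called 0 genes, with 1390 at an unadjusted p under 0.05. DESeq2 called 43 and limma-voom 0. The edgeR count was 53 without Western diet postpartum replicate 2, 3 without Western diet postpartum replicate 1, and 1 without control diet postpartum replicate 3 or without the control pair. Camera with the preset correlation called 15 lists, none of which held with an estimated correlation (lowest adjusted p = 0.152). Genes called on 1 diet and not on the other are thus not shown to differ between the diets.

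Averaged over the diets, genes higher postpartum were Thbs1 (1.70), Tnc (1.59), Nppb (1.63, adjusted p = 0.0229), Ccl2 (1.10), E2f1 (0.93), Mthfd2 (0.93) and Uck2 (0.80). Postn, a matrix protein of activated fibroblasts (0.59), Stbd1 (0.56), Cd68 (0.54), Col5a2 (0.50), Col1a1 (0.48) and the collagen cross-linker Loxl1 (0.35) rose as well. Lower postpartum were Ciart (-1.51), Dbp (-1.16), Tcap (-0.76), Ccbe1 of lymphatic growth (-0.60), Fgf16 (-0.59) and Bhlhe41 (-0.56). Foxo3 (-0.43), the clock gene Nr1d2 (-0.40), Rnf166 (-0.40), Rnf207 (-0.33) and Myh7 (-0.24, adjusted p = 0.0187) fell too. Over both diets the circadian clock list had 8 of 20 genes fallen over all genes, and 10 fallen and 3 risen adjusted over the list alone. Its median was -0.27 (camera adjusted p = 6.40e-09, and adjusted p = 0.0495 with an estimated correlation). The labels give no time of collection, so the falls of clock genes are not tied to pregnancy here. The same limit holds for other genes with a daily rhythm, which were not set apart. The extracellular matrix and fibrosis list stood at 0.33, with 14 of 41 genes risen over all genes and 25 adjusted over the list alone (adjusted p = 6.80e-27, but adjusted p = 0.0608 with an estimated correlation). The fetal and hypertrophic gene program stood at 0.30, with 3 risen and 1 fallen over all genes (adjusted p = 2.86e-06, but adjusted p = 0.0608 with an estimated correlation). Cell cycle and DNA replication stood at 0.55, with E2f1 and Birc5 (1.13) risen among 32 genes (adjusted p = 2.39e-12, but adjusted p = 0.225 with an estimated correlation). Macrophage and monocyte markers stood at 0.28, with 3 of 18 genes risen over all genes (adjusted p = 2.15e-08, but adjusted p = 0.203 with an estimated correlation).

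For pregnancy averaged over the diets 276 genes passed, 160 higher and 116 lower, with 2721 at an unadjusted p under 0.05. Of the 16 lists called, 1 held with an estimated correlation and 5 were lost without at least 1 library. Of the 27 named calls 16 held without each library in turn, and those that did not were Asns, Birc5, Ccl2, Cd68, Col1a1, E2f1, Myh7, Nppb, Nr1d2, Phgdh and Postn. The gene count was 488, 72 and 82 without control diet nonpregnant replicates 1, 2 and 3, and 174 and 93 without control diet postpartum replicates 1 and 3. It was 151, 98 and 102 without Western diet nonpregnant replicates 1, 2 and 3, and 52, 567 and 149 without Western diet postpartum replicates 1, 2 and 3. Without the control pair it was 293.

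**Figure D4:**
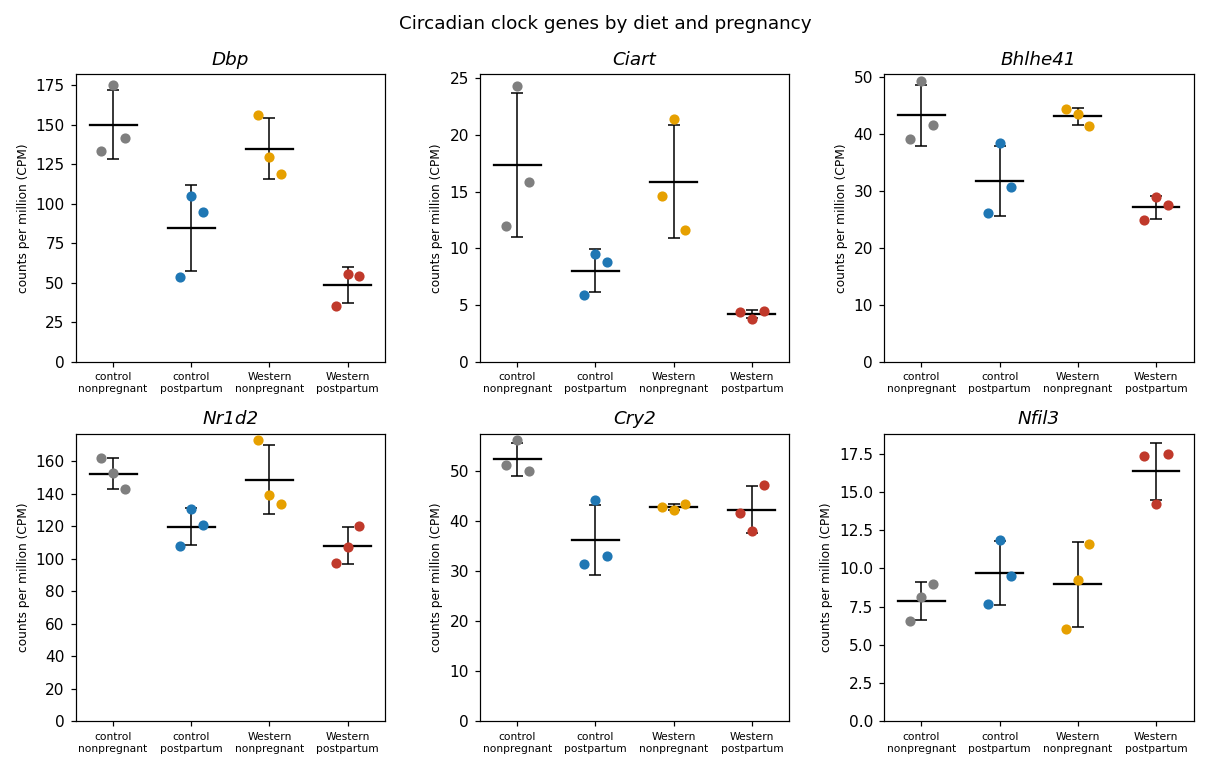
Normalised CPM (vertical axis) of 6 circadian clock genes in the 4 groups; points are libraries, the horizontal line is the group mean and the bar 1 SD (n = 3). Dbp averaged 150.1 and 134.8 CPM in nonpregnant and 84.4 and 48.3 CPM in postpartum hearts on the control and the Western diet.

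Averaged over pregnancy states, the Western diet raised Angptl4 (2.31), Pdk4 (1.77), Acot1 (1.69), Mthfd2 (1.31), Acot2 (0.93), the gluconeogenic Fbp2 (0.86) and Scn4b (0.82). Adh1 (0.77), Asns (0.74), Acsf2 (0.59), Pex11a (0.54), Decr1 (0.46), Lims2 (0.40) and Ramp2 (0.33) were higher as well. With edgeR's robust option the calls of Angptl4 and Pdk4 were lost (adjusted p = 0.0628 and 0.0677). Of 20 alternatives in all, that of Angptl4 was lost under 2 and that of Pdk4 under 1. The diet lowered Abat (-1.23), Plekhh1 (-1.19), Lgi3 (-1.17), Lrrc4b (-0.91), Adgrb2 (-0.87), Ston2 (-0.84) and Tmem35a (-0.67). Ndrg4 (-0.56), Fgf16 (-0.51), Cacna1h (-0.46) and Gja1 (-0.45) fell too. Nppa fell by 0.91 (adjusted p = 0.00714), from 75.3 ± 12.6 to 38.6 ± 13.8 CPM without pregnancy and from 92.9 ± 7.59 to 51.7 ± 9.36 CPM after it (SD, n = 3). Fatty acid oxidation and PPAR alpha targets had 21 of 40 genes risen over all genes, and 35 risen and 1 fallen adjusted over the list alone. Their median was 0.33 (camera adjusted p = 3.53e-52, and adjusted p = 0.0226 with an estimated correlation). Endothelial markers had 6 of 15 risen by either adjustment, among them the fatty acid carrier Fabp4 (0.38), Ly6c1 (0.52) and Pecam1 (0.21). They stood at 0.14 (adjusted p = 1.40e-10, and adjusted p = 0.0378 with an estimated correlation). Cardiac ion channels and gap junctions had 2 of 26 fallen and Scn4b risen, and 11 fallen and 1 risen adjusted over the list alone. They stood at -0.21 (adjusted p = 2.45e-05, and adjusted p = 0.0226 with an estimated correlation). Sterol and fatty acid synthesis stood at -0.16 (adjusted p = 0.00165, but adjusted p = 0.428 with an estimated correlation). The list lay at 0.64 in control diet postpartum replicate 3, and without that library the median was -0.13 (adjusted p = 0.00587). Antioxidant and NRF2 targets had a median of 0.09 and a mean of -0.07 with camera's direction up (adjusted p = 0.00334, but adjusted p = 0.408 with an estimated correlation). Without Western diet postpartum replicate 3 that median was 0.04.

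For diet averaged over pregnancy states 214 genes passed, 153 higher and 61 lower, with 2210 at an unadjusted p under 0.05. Of the 31 named calls 25 held without each library in turn, and those that did not were Atf4, Cacna1h, Fabp4, Ly6c1, Pecam1 and Trib3. Camera called 12 lists, of which 3 held with an estimated correlation and 3 were lost without at least 1 library. The gene count was 127 without control diet postpartum replicate 1, and 135, 378 and 106 without Western diet postpartum replicates 1, 2 and 3. It was 83 and 115 without Western diet nonpregnant replicates 2 and 3, 100 without control diet nonpregnant replicate 2, and 242 without the control pair.

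Tnc rose and Rnf166 fell after pregnancy on both diets, the genes shared by those calls. Chance would give 0.114 shared rises and 0.0116 shared falls. Of the 37 genes called on the control diet 35 had the same sign on the Western diet, and of the 91 called there 73 had the same sign on the control diet. Across the 15476 genes, which are not independent replicates, the postpartum changes on the diets correlated with Pearson r = 0.146 and Spearman rho = 0.203. That r was 0.0458 without Western diet postpartum replicate 1 and 0.229 without Western diet nonpregnant replicate 3. For the diet, Adh1, Pex11a, Scn4b and Lims2 were among the genes that rose, and Ndrg4 and Abat fell, in both pregnancy states. There were 5 shared rises and 2 shared falls where chance would give 0.0452 and 0.00465. Of the called genes 120 of 136 and 9 of 9 had the same sign in the other state. The diet changes correlated across genes with Pearson r = 0.0548 and Spearman rho = 0.112. This r was -0.0278 without control diet nonpregnant replicate 1, -0.0117 without Western diet nonpregnant replicate 2 and 0.149 without Western diet nonpregnant replicate 3.

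Of the 35 lists tested, 11 did not pass camera in any of the 8 comparisons. The pregnancy and lactation hormone signalling list stood at -0.08 on the control (adjusted p = 0.977) and 0.06 on the Western diet (adjusted p = 0.866) postpartum. Its lowest adjusted p of the 8 was that of the averaged diet effect (median -0.10, adjusted p = 0.0631). For the others the comparison with the lowest adjusted p is given. On the control diet postpartum these were the heat shock proteins (median 0.03, adjusted p = 0.329), the smooth muscle and pericyte markers (0.17, adjusted p = 0.112) and the white adipocyte markers given above. On the Western diet postpartum it was the neutrophil markers (0.29, adjusted p = 0.489). For the averaged pregnancy effect it was the erythroid markers (0.23, adjusted p = 0.0725) and the lymphatic endothelial markers (0.07, adjusted p = 0.505). For the averaged diet effect it was the atrial myocyte markers (median 0.02 with a mean of -0.15 and camera's direction down, adjusted p = 0.146). There the skeletal muscle markers had a median of -0.01 with a mean of 0.07 and camera's direction up (adjusted p = 0.853). Without pregnancy it was angiogenesis and endothelial signalling (0.01, adjusted p = 0.212). In the interaction it was the renin-angiotensin, adrenergic and natriuretic signalling list (0.08, adjusted p = 0.112).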

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

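The explanations weighed in this part were tested with tests chosen after the results were seen. The lists below differed between the diets in their response to pregnancy by camera's test of the interaction with a preset correlation, and no such call held with an estimated correlation. Of the 15 preset calls 4 were lost without at least 1 library, as given beside each. The demand below that a gap hold without each library in turn was added after the first values were seen.

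The extracellular matrix and fibrosis list had a median interaction, Western minus control diet, of -0.31 (-0.3089; adjusted p = 0.369 with an estimated correlation), and the fibroblast markers of -0.43 (-0.4251; adjusted p = 0.152). On the control diet the matrix list rose after pregnancy, and 3 explanations of that rise were tested. Fat tissue in control diet postpartum replicate 3 is argued against, since the list's median was 0.4583 without that library against 0.4843 with it. A lower share of cardiomyocytes would raise other cell types alike. Against a rise shared by all of them, endothelial markers stood at 0.0243, below the matrix list by more than 2 SE of the difference (0.146), also without each library in turn. This SE and the next are over genes, which are not independent replicates, and do not measure the spread between hearts. Macrophage and monocyte markers did rise by camera's preset test. The cardiac ion channels had a preset call (adjusted p = 0.0118), lost at a median of -0.0505 without control diet postpartum replicate 1 (0.0682). Of the 12 preset calls on the control diet, 7 were up and 5 down. The 12 included adult sarcomere and calcium handling, fatty acid oxidation and PPAR alpha targets and the mitochondrially encoded genes. Each of these calls was lost without at least 1 library. A lower share is therefore not excluded. More fibroblasts cannot be told apart from more matrix transcription per cell: fibroblast markers outside the matrix list stood at 0.1843, a gap that passed 2 SE (0.206) with all libraries but not without control diet postpartum replicate 3 (gap 0.161 against 0.227) or control diet nonpregnant replicate 1 (0.238 against 0.239).

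The clock genes that peak with Dbp stood at a median of -0.4833 postpartum on the control diet. A single library as the source is argued against, since the median nearest to 0 with 1 library left out was -0.3939, without control diet nonpregnant replicate 2. Collection at another time of day remains open and could account for the pattern: 5 genes of the opposite phase (Arntl, Clock, Npas2, Cry1 and Nfil3) stood at 0.297, although at 0.05 without control diet postpartum replicate 1. The labels give no collection time, so a shift of the clock by pregnancy, delivery or nursing stays as open and was not tested. On the Western diet the same sets stood at -0.53 and 0.68. Between the diets after pregnancy they stood at -0.15 (2 of 11 genes above 0) and 0.37 (5 of 5). A difference in collection time is thus not excluded for that comparison either.

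Sterol and fatty acid synthesis genes stood at a median of -0.23 on the Western diet after pregnancy. Fat tissue in control diet postpartum replicate 3 is a likely contributor, since without that library the list stood at -0.096 (-0.10; camera adjusted p = 0.134). There Ucp1 stood at 73.1 CPM, Cfd at 72.6 CPM, Car3 at 64.1 CPM and Adipoq at 19.6 CPM, while Lpl and Fabp4, which heart also expresses, stood at 5950 and 575 CPM beside medians of 5563 and 576 CPM elsewhere. A fall with the diet that is also there without pregnancy cannot be told apart, since the list stood at -0.107 in nonpregnant hearts (adjusted p = 0.0922).

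Other lists are given as values, the median interaction on the log2 scale with its adjusted p with an estimated correlation. Interferon-stimulated genes differed by -0.4876 (adjusted p = 0.369), and by -0.29 without Western diet nonpregnant replicate 1. Lymphocyte markers differed by -0.8325 (adjusted p = 0.369), by -0.36 with the filter of 1 CPM, where the preset call was lost (adjusted p = 0.135), by -0.55 and -0.42 without Western diet postpartum replicates 2 and 3, by -0.47 without control diet postpartum replicate 3 and by -0.48 without control diet nonpregnant replicate 3. Cell cycle and DNA replication differed by -0.6293 (adjusted p = 0.369), by -0.39 without control diet postpartum replicate 1, and by -0.41 and -0.40 without control diet nonpregnant replicates 2 and 3. Nerve and Schwann cell markers differed by -0.5428 (adjusted p = 0.369; camera's preset call was lost without control diet postpartum replicate 3 and control diet nonpregnant replicate 1 together, adjusted p = 0.109). Macrophage and monocyte markers differed by -0.2619 (adjusted p = 0.369), by -0.17 and -0.41 without Western diet nonpregnant replicates 1 and 3, and by -0.46 without control diet nonpregnant replicate 1. Unfolded protein and integrated stress response genes differed by -0.0872 (adjusted p = 0.677; preset adjusted p = 0.0491, but 0.632 without control diet postpartum replicate 3, 0.133 and 0.104 without control diet nonpregnant replicates 1 and 2, 0.0725, 0.077 and 0.0625 without Western diet postpartum replicates 1, 2 and 3, and 0.0504 and 0.165 without Western diet nonpregnant replicates 1 and 2), with medians of -0.18 and -0.02 without control diet postpartum replicates 1 and 3, -0.14 and -0.16 without Western diet postpartum replicates 2 and 3, and -0.15 without Western diet nonpregnant replicate 1 or control diet nonpregnant replicate 2. The cytokines and acute inflammation list differed by 0.3108 (adjusted p = 0.152), and by 0.47 without control diet nonpregnant replicate 2. Fatty acid oxidation and PPAR alpha targets differed by 0.229 (adjusted p = 0.369). Glucocorticoid and atrophy targets differed by 0.1544 (adjusted p = 0.369; preset adjusted p = 0.0491, but 0.295 and 0.136 without control diet postpartum replicates 2 and 3, 0.168 without control diet nonpregnant replicate 3, 0.0881 and 0.13 without Western diet postpartum replicates 1 and 2, and 0.0941 and 0.0978 without Western diet nonpregnant replicates 1 and 3), with medians of 0.25 and 0.04 without control diet postpartum replicates 1 and 3, 0.04 without Western diet postpartum replicate 1 and 0.10 without control diet nonpregnant replicate 3. Mitochondrially encoded genes differed by 0.1514 (adjusted p = 0.369). Glucose uptake and glycolysis differed by 0.0993 (adjusted p = 0.369), by 0.05 without Western diet postpartum replicate 3 or Western diet nonpregnant replicate 1, by 0.07 without control diet postpartum replicate 3, and by 0.02 and 0.06 without control diet nonpregnant replicates 2 and 3. Antioxidant and NRF2 targets differed by 0.0762, with a mean of -0.12 and camera's direction up (adjusted p = 0.369; preset adjusted p = 0.0122, but 0.053 without control diet nonpregnant replicate 3, where the median was 0.04). The nuclear-encoded respiratory chain differed by 0.0499 (adjusted p = 0.755; preset adjusted p = 0.0491, but 0.0825 and 0.442 without control diet postpartum replicates 1 and 3, 0.161 and 0.868 without control diet nonpregnant replicates 2 and 3, 0.333 and 0.0878 without Western diet postpartum replicates 1 and 3, and 0.272 without Western diet nonpregnant replicate 3), with medians of 0.02 and 0.08 without Western diet postpartum replicates 1 and 2, 0.02 without control diet postpartum replicate 3, and 0.10, 0.03 and 0.0017 without control diet nonpregnant replicates 1, 2 and 3. Under other settings of filter or tool the preset calls of the respiratory chain, of glucocorticoid and atrophy targets and of the stress response were lost too (adjusted p = 0.0555 to 0.0765, 0.0559 to 0.0661 and 0.056 to 0.0889).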

How the results depend on the processing

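Leaving out control diet postpartum replicate 3 and control diet nonpregnant replicate 1 together was chosen after the data were seen; the other alternatives were set before. The comparisons are given in the order control diet pregnancy, Western diet pregnancy, diet after pregnancy, diet without pregnancy, both factors, interaction, averaged pregnancy and averaged diet. DESeq2 size factors in edgeR, library sizes without mitochondrial genes and limma-voom left every gene count within 1.5 times of its value. Without a filter on low counts 744, 933, 1048, 454, 1315, 506, 1262 and 1029 genes passed. Then 29761 genes were tested and the estimated prior degrees of freedom, 5.74 with the filter, became infinite. Each gene's spread was thus taken wholly from the trend over abundance and not from its own libraries. Of these calls 720, 912, 1008, 443, 1305, 483, 1234 and 1008 were among the genes tested with the filter. DESeq2 called 184, 361, 456, 95, 779, 43, 615 and 484. With a fit of only the groups compared, which has fewer libraries to estimate the spread, the first 5 counts were 6, 47, 71, 0 and 136. The filter of 1 CPM gave 5 for diet without pregnancy, and edgeR's robust option gave 1 for the interaction. Without the 2 control diet libraries named above the counts were 74 for control diet pregnancy, 15 for diet without pregnancy and 1 for the interaction; the cause was not tested. With 1 library left out the counts ran from 0 to 205, 0 to 472, 30 to 490, 0 to 4, 87 to 764, 0 to 53, 52 to 567 and 83 to 378; the libraries are named in the report. Lists called fell from 12, 14, 15, 14, 17, 15, 16 and 12 to 3, 1, 0, 0, 4, 0, 1 and 3 with an estimated correlation and to 6, 1, 6, 1, 6, 0, 8 and 4 with fry, which asks another question; with 1 library left out they ran from 10 to 16, 12 to 17, 11 to 18, 11 to 16, 15 to 18, 12 to 21, 13 to 19 and 9 to 17. The correlation of pregnancy effects across genes was -0.0053 without a filter, 0.238 with the 1 CPM filter, 0.2307 with only the groups compared and 0.0458 to 0.2285 with 1 library left out. That of diet effects was -0.0106, 0.1669, 0.1392 and -0.0278 to 0.1488, with -0.0117 without Western diet nonpregnant replicate 2, and 0.0055 without those 2 control diet libraries. The filters change which genes enter, and the cause was not tested. Of the values of named genes under the alternatives, 2943 kept their direction and side of the threshold, 590 no longer passed it, 65 newly passed it, and 0 turned their direction. Genes named for a small p in these same libraries could hardly turn, so that 0 is no support. The 2943 include genes that passed in neither setting. No paired analysis was possible because the replicate numbers follow only the order of deposit. Depth limits genes near the floor of 0.102 to 0.132 CPM, and 53.7% of simulated 1.5-fold changes were recovered.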

Other observations

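No test in the next paragraph or among the regroupings was chosen after its result was seen, but the grouping of genes within the stress response list was.

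Within the unfolded protein and integrated stress response list, some members of amino acid and one-carbon supply passed the test; they were grouped here after the values were seen and were not tested as a group. Averaged over pregnancy states the Western diet raised Mthfd2 of mitochondrial folate metabolism (1.31) and the asparagine synthetase Asns (0.74), calls that held without each library in turn. The stress kinase inhibitor Trib3 (0.52) and the regulator Atf4 (0.28) passed too, but their calls ended without 10 and 5 of the 12 libraries, each left out alone. In all 5 of 22 members rose over all genes, and adjusted over the list alone 6 rose and 3 fell. Averaged over the diets, Mthfd2 was higher postpartum (0.93), a call that held without each library. Asns (0.57) and the serine synthesis enzyme Phgdh (0.73, adjusted p = 0.04996) passed but ended without 6 and 11 libraries. In Western diet postpartum against control diet nonpregnant hearts, Mthfd2 (2.24), Phgdh (1.48) and Asns (1.31) rose and held without each library, while Psat1, also of serine synthesis (0.87, adjusted p = 0.0467), ended without 5 of the 6 libraries compared. The 4 members of the list with the smallest interaction p act in the endoplasmic reticulum. Their interaction values were -0.64 for Pdia6 (adjusted p = 0.359), -1.05 for Sdf2l1 (0.492), -0.88 for Manf (0.501) and -0.43 for Calr (0.442). The median of the whole list was -0.0872, so genes picked for a small p do not stand for its chaperones as a class. Without control diet postpartum replicate 3, the library with fat tissue genes, the 4 values were -0.48, -0.54, -0.39 and -0.33. The whole list lay at 0.31 in that library against -0.16 and -0.04 in its replicates, and its median interaction was -0.02 without it (adjusted p = 0.632).

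Regrouping the libraries gave the following. Averaged over diets, 276 genes differed with pregnancy and at most 16 in the other regroupings. The regrouping with 16 kept the Western diet libraries of each pregnancy state together. The real grouping was the only 1 of 100 as large, which argues against chance but does not exclude it. Averaged over pregnancy states, 214 genes differed with diet and at most 124 in the others (1 of 100). A further regrouping gave 83. The regroupings with 124 and 83 kept the postpartum libraries of each diet together and mixed only the nonpregnant ones. Their counts can thus carry the diet difference after pregnancy, and do not show what fully wrong groupings call. Chance is not excluded there either. For the interaction, 0 genes passed, so 100 of 100 regroupings had to give as many (highest 6), and this says nothing about chance. For 3 against 3 libraries the 10 splits are too few for a share under 0.05: real counts and the highest of the others were 37 and 4 (control diet pregnancy), 91 and 0 (Western diet pregnancy), 136 and 0 (diet after pregnancy), 9 and 5 (diet without pregnancy), and 406 and 3 (both factors), the real split being 1 of 10 each time. The number of lists called with the preset correlation was not beyond regroupings where these were enough to tell: 15 lists for the interaction with a highest other of 19 (20 of 100 as large), 16 for pregnancy with 20 (13 of 100) and 12 for diet with 19 (40 of 100). In each of these the other regroupings called a median of 11 lists, so the preset test calls many lists when libraries are regrouped. Regroupings can keep part of a real difference, so this median is no rate of false calls. For 3 against 3 libraries, again too few splits, the real and highest other list counts were 12 and 17 (5 of 10), 14 and 10 (1 of 10), 15 and 17 (3 of 10), 14 and 14 (2 of 10) and 17 and 13 (1 of 10) in the same order. The correlations across genes were 0.146 for pregnancy with a highest other of 0.193 (8 of 100) and 0.0548 for diet with 0.171 (23 of 100). These shares do not argue against chance.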
